A study of Mus musculus with 28 samples.

How the data were processed

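RNA was sequenced from laser-captured layers of the hippocampus of 3 adult male Amigo2-EGFP mice, which carry a green fluorescent reporter. From each mouse, the cell body layer and the dendritic layer of CA1, CA2, CA3 and the dentate gyrus (DG) gave 8 libraries, or 24 in all. Per the labels' protocols, tissue sections were 8 µm thick, 5 ng of RNA went into each cell body library and 1 ng into each dendritic library, and libraries were amplified for 16 PCR cycles. The 8 libraries of a mouse were prepared and sequenced together on a NextSeq 500 as 100 bp paired reads with a target of 50 M reads, so mouse and library batch were the same factor apart from libraries that were remade. Input amount and compartment could not be separated.

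The submitters' processing notes list FastQC, cutadapt, STAR 2.5.1b, Salmon 0.9.1, featureCounts 1.5.1, R 3.4.2, limma 3.32.2, DESeq2 1.18.1 and the mm10 build, without saying which step used which. The annotation release behind the gene and transcript names is not given in the sources used here. The deposited gene values are log2 values of Salmon read estimates, per the file headers, which also name a median normalization. Checked on the values, each was the log2 of an estimate plus 1, shifted by 1 constant per library, with a floor at 0. That constant could be recovered exactly for 11 libraries and approximately for the others. The deposited transcript table holds log2 values of the same 24 libraries for transcripts that the file name calls detected. The values are estimates and not read counts, so no counting interval was computed, and reads shared between a gene and a close copy may have been split between them. This applies above all to ribosomal protein genes and other families with pseudogenes. The library kit is not stated to have been counted by strand, so a gene and an antisense partner could not be told apart.

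Another 4 dendritic libraries, repeats for CA2 and DG of mice 502 and 492, had no column of their own in the deposited tables. Per the labels' protocols, libraries with a low mapped share were remade. That the repeats are these libraries is an inference, and the sources used here do not say whether the table columns of those animals hold the first library, the remade one or both. If they hold remade libraries, part of the CA2 and DG dendritic columns come from another preparation. Batch would then be partly mixed with the comparisons of CA2 and DG dendrites. A table of microarray values with 12 array columns was not used here, because its columns match no sequenced library.

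Genes were tested when their value was at least log2(10) in at least 3 libraries, which left 24911 of 49341 genes. limma 3.58.1 (R 4.3.3, statmod 1.5.0) was fitted to the deposited log2 values with 8 groups of 3 libraries and mouse as a block, leaving 14 residual degrees of freedom, with a trended and robust estimate of the spread. All 24 libraries shared that estimate. There were 14 comparisons: dendritic against cell body layers as the mean of 4 subregions and within each subregion, each subregion against the mean of the other 3 in each compartment, and the difference between compartments in the CA2 effect. The p-values were two-sided, adjusted by the Benjamini-Hochberg method over the genes tested, and called at an adjusted p below 0.05. A gene was counted as detected in a group when it had at least 10 normalized counts in all 3 mice. Standard errors (SE) are those of the limma fit, and standard deviations (SD) are over 3 mice.

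Gene lists of cell type markers, complexes and pathways, 41 in all, were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. The same test with an estimated correlation, and limma's fry, were run beside it. Camera compares a list with the other genes, whereas fry asks only whether the genes of a list move one way on balance. Transcripts were tested with limma's diffSplice for unequal change within a gene, over 10025 genes with 34762 transcripts. The comparisons, tests, gene lists and most alternatives were chosen before the data were examined. So was the rule for naming genes. For the mean comparison of compartments and each dendritic comparison, the 8 largest differences each way were taken. Each had to have an adjusted p below 0.05, the same direction in all 3 mice, a mean of at least log2(100) on the higher side, and no predicted or clone name. The 4 largest each way were taken for the difference between compartments, and the 4 largest higher for each cell body comparison. Up to 4 genes with the smallest adjusted p were taken from each called list, and Amigo2, Rgs14, Pcp4 and Mcu were always reported. Some of these genes are mentioned by name and the others enter the counts. Individual results of a few genes that this rule selects are not reported here and were left out of the named-gene counts of the alternatives, while the list tests kept every member.

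The mouse block was used because the 8 libraries of a mouse came from the same animal. As a check, after group means were removed, the median correlation between libraries of the same mouse was 0.022 against -0.011 between mice. Over 0.1 were 2 of 84 same-mouse pairs, and 24 of 24 libraries were on average closest to their own mouse.

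Alternatives were quantile normalization, scaling to library totals, no filter, a filter of 100 in place of 10, 16 added before the log, no mouse block, library weights, and only the libraries of the compartment or subregion compared. For detection, 2 of 3 mice and a limit of 100 were tried, and for transcripts, Simes-adjusted tests. The astrocyte and oligodendrocyte list means were also tried as covariates, and the 4 dendritic libraries with a repeat, and each mouse in turn, were left out. Median scaling, scaling to totals outside the mitochondrial genome, and leaving out the CA1 dendritic libraries of mice 492 and 496 were added after seeing the data. The scripts were tested on simulated data made from the means and spread of these libraries. For the mean comparison of compartments, 31.3%, 53.7% and 75.8% of genes changed by a log2 value of 1, 2 and 3 were recovered, with 4 false calls among 24911 genes. For CA2 dendrites against the other dendrites, 14.9%, 35.8% and 40.9% were recovered, again with 4 false calls. For CA2 dendrites against CA2 cell bodies, 8.96%, 26.9% and 31.8% were recovered, with 3 false calls. For transcripts, 26 of 100 genes with a log2 change of 2 and 88 of 100 with a change of 4 were recovered in the mean comparison, with 16 false calls among 10025 genes. In CA2 dendrites these numbers were 2 and 32, with 6 false calls. In each gene simulation only 67, 67 and 66 genes carried changes of 1, 2 and 3. In the data 11269, 640 and 6979 genes were called in these comparisons, in the order given. With fewer changed genes the adjusted threshold is stricter than in the data. The recovered shares and false calls of genes therefore cannot be carried over to the counts in the data. Genes missed by a test are still not shown to be equal.

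Gene positions are on GRCm38 from GENCODE M21, matched by symbol. Of 992 named and listed genes, 985 had 1 position and 4 had no match. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for positions and plots.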

Results

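The libraries covered 4 hippocampal subregions, CA1, CA2, CA3 and DG, and 2 compartments of each. Cell body layers were the stratum pyramidale of the CA fields and the granule cell layer of DG. Dendritic layers were the stratum radiatum and the molecular layer, which also hold glia, vessels, interneurons and passing axons. They are called dendrites here, as in the labels. Each of the 8 groups had 3 libraries, from mice 492, 496 and 502. The question, as the title of the series puts it, was whether subregions differ in the RNAs of their dendrites, with attention to mitochondria in CA2. All log2 differences are between means of 3 mice per group, and every gene named as higher or lower had an adjusted p below 0.05 in limma.

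Estimated reads per library were 35.4 to 53.6 M in cell bodies (43.8 ± 4.68, SD, n = 12) and 32.6 to 67.4 M in dendrites (51.8 ± 9.67, SD, n = 12). RNAs of the mitochondrial genome took 4.21% to 9.08% of normalized counts in cell bodies and 29.5% to 46.9% in dendrites. The 10 most abundant genes took 5.01% to 9.62% and 26.8% to 42.1%. Detected genes numbered 16766, 15786, 16386 and 17733 in the cell bodies of CA1, CA2, CA3 and DG, and 13483, 15448, 14975 and 16209 in their dendrites. At a limit of 100 counts in place of 10 the order turned, with 11364, 11524, 11412 and 11511 in cell bodies and 11462, 11659, 11651 and 11915 in dendrites. All 4 dendritic groups shared 12347 genes, of 17880 detected in any of them. The first principal component, over 13188 genes, held 39.4% of the variance and placed all cell body libraries at -88.8 to -59.4 and all dendritic libraries at 57.5 to 92.6. The CA1 dendritic libraries of mice 492 and 496 had the highest medians (9.85 and 9.82, with the other dendritic libraries at 8.93 to 9.53) and the fewest genes with at least 10 counts (15842 and 16570).

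**Figure D1:**
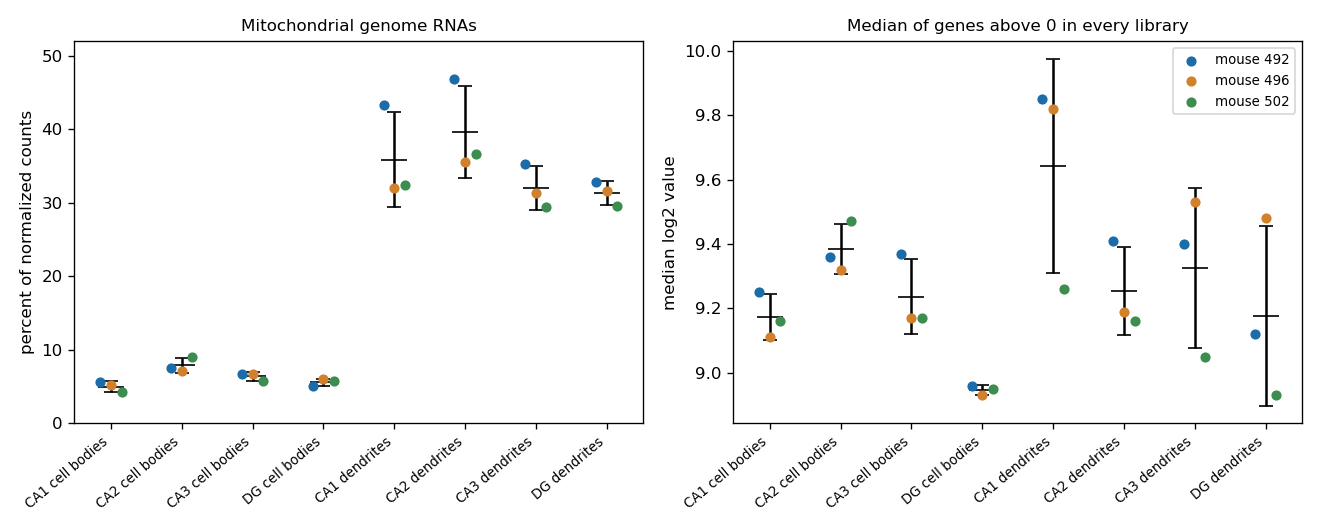
Percent of normalized counts from the mitochondrial genome (left) and median deposited log2 value of the genes above 0 in every library (right), for 8 groups; points are libraries coloured by mouse, and bars are mean ± SD of 3 mice. Dendritic libraries lie at 29.5% to 46.9% on the left, and the CA1 dendritic libraries of mice 492 and 496 are highest on the right, at 9.85 and 9.82.

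Dendritic layers were set against cell body layers to ask which RNAs each compartment holds. Slc1a2 (chromosome 2, 102658659 to 102790784), the glial glutamate transporter, was higher in dendrites by a log2 difference of 3.26 ± 0.061 (SE, adjusted p = 8.27e-22). Camk2a (chromosome 18, 60925618 to 60988152), which encodes a kinase subunit and is a known dendritic mRNA, was higher by 2.53 ± 0.059 (SE, adjusted p = 1.45e-20). Under quantile normalization its difference was 1.00. Shank1 (chromosome 7, 44310253 to 44360572), a scaffold of excitatory synapses, was higher by 3.00 ± 0.071 (SE, adjusted p = 1.81e-20). Slc9a4 (chromosome 1, 40580081 to 40630725), a sodium-proton exchanger, was lower by -4.83 ± 0.48 (SE, adjusted p = 7.1e-09). The largest difference was that of Ttr (chromosome 18, 20665280 to 20674321), the transthyretin gene of the choroid plexus, at 6.15 ± 0.579 (SE, adjusted p = 2.69e-09). Acta2 of vessel walls followed with 5.49, and Popdc3 and Thpo were lower by -4.68 and -4.40.

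The median log2 difference of all genes was -0.20 between compartments (-0.18 under quantile normalization and -0.63 under scaling to totals), and list medians are also given relative to it. Markers of non-neuronal cells and of interneurons were higher in dendrites. All 14 astrocyte markers were higher (14 adjusted over the list alone), with a median log2 difference of 3.34, or 3.55 relative to all genes, including Aqp4 (4.02) and Gfap (4.04). So were all 12 microglia markers (12 adjusted over the list alone; median 3.55, Csf1r 3.65, P2ry12 4.08), all 13 oligodendrocyte markers (13 adjusted over the list alone; median 2.92, Mbp 2.81) and all 11 endothelial markers (11 adjusted over the list alone; median 3.45, Flt1 3.44). Of 14 interneuron markers, 13 were higher and 1 did not pass (13 adjusted over the list alone), with a median of 1.92, a Gad2 difference of 2.36 and an Erbb4 difference of 1.88. These 5 lists passed camera with adjusted p = 8.05e-19, 4.38e-15, 5.1e-15, 1.74e-12 and 8.88e-11, and with an estimated correlation with adjusted p = 0.00184, 0.00184, 0.0292, 0.00021 and 0.0216.

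Neuronal and housekeeping groups moved in both directions. The 13 mRNAs of the mitochondrial genome were all higher in dendrites (13 adjusted over the list alone), with a median of 2.91, or 3.12 relative to all genes, and with mt-Co3 at 2.90 (camera adjusted p = 1.23e-14). Under quantile normalization their median was 0.81, 11 were higher and mt-Co1, ranked first in every library, had a difference of 0 by construction. Of 81 cytosolic ribosomal protein genes, 66 were higher, 1 was lower and 14 did not pass (67 higher adjusted over the list alone; median 0.71, Rpsa 1.59, camera adjusted p = 1.46e-13). Of 26 postsynaptic scaffold genes, 17 were higher and 4 lower (17 and 5 adjusted over the list alone), with a median of 0.89, or 1.10 relative to all genes, and with Shank3 at 2.81 and Dlgap3 at 2.35 (camera adjusted p = 5.26e-07). Of 16 mRNAs known from textbooks as dendritic, 12 were higher and 4 lower (12 and 4 adjusted over the list alone; median 1.57, Map2 2.67, Ddn 2.12, camera adjusted p = 4.61e-06), and without the members that another list also holds the textbook call was lost. Of 34 proteasome genes, 33 were lower (33 adjusted over the list alone; median -1.01, Psmb5 -1.70, Psmd14 -1.44, camera adjusted p = 9.89e-12). Of 78 mitochondrial ribosome genes, 55 were lower and 23 did not pass (57 lower adjusted over the list alone; median -0.77, Mrps26 -1.33, camera adjusted p = 4.04e-09). None of these 6 list calls held with an estimated correlation (adjusted p = 0.122, 0.344, 0.344, 0.16, 0.155 and 0.155 with an estimated correlation, in the order given).

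In all, 11269 of 24911 genes differed between compartments, 4941 higher and 6328 lower in dendrites, against 3596 and 9940 under scaling to totals. With the astrocyte and oligodendrocyte marker means as covariates, limma called 0 genes. These means had correlations of 0.988 and 0.912 with compartment over the 24 libraries, so this fit had little left to compare.

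**Figure D2:**
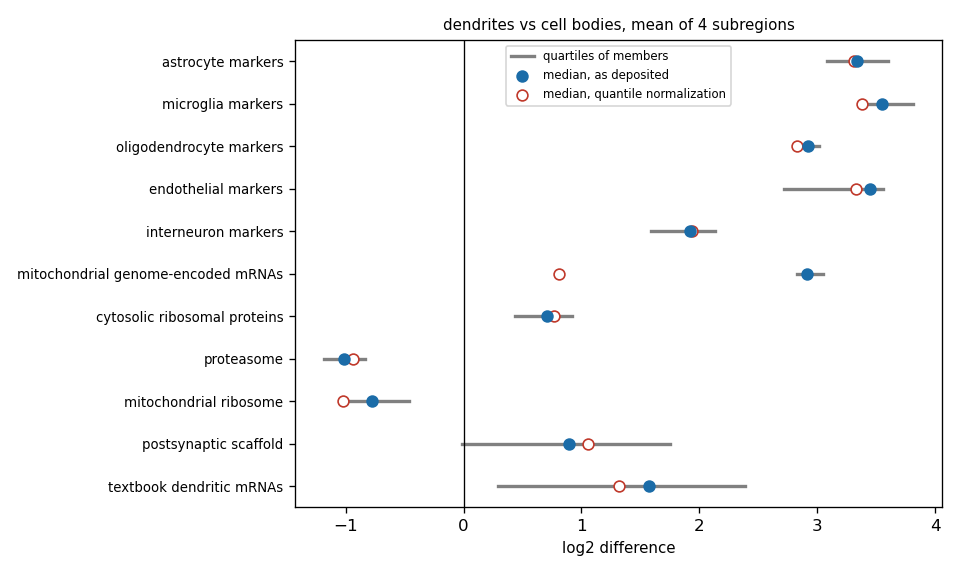
Log2 difference between dendrites and cell bodies (horizontal axis, mean of 4 subregions, 3 mice per group) for 11 gene lists; filled points are list medians of the deposited values, open points are medians under quantile normalization, and grey bars span the quartiles of the members. Astrocyte markers have a median of 3.34 and the proteasome -1.01, and the mitochondrial genome moves from 2.91 to 0.81 under quantile normalization.

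The same contrast was made within each subregion to see where it differed in size. Most of the subregion's own pyramidal markers were lower in the dendrites of CA1, CA2 and CA3, and 5 of 12 granule cell markers were lower in those of DG. Of 15 CA2 markers, 11 were lower in CA2 dendrites than in CA2 cell bodies (12 adjusted over the list alone), with a median of -3.02 (adjusted p = 0.00767 with an estimated correlation). Of 10 CA1 markers, 7 were lower and 1 higher in CA1 (7 and 1 adjusted over the list alone), with a median of -1.69 (adjusted p = 0.0247 with an estimated correlation). Of 8 CA3 markers, 6 were lower in CA3 (6 adjusted over the list alone), with a median of -2.11 (adjusted p = 0.0198 with an estimated correlation). Of 12 granule cell markers, 5 were lower in DG (5 adjusted over the list alone), with a median of -2.20 (camera adjusted p = 0.00175, and adjusted p = 0.171 with an estimated correlation). All 14 astrocyte markers were higher in the dendrites of each subregion (14 adjusted over the list alone in each), with medians of 3.62, 3.08, 2.94 and 4.02 in CA1, CA2, CA3 and DG. Mcu (chromosome 10, 59446984 to 59616692), the pore of the mitochondrial calcium uniporter, was lower in CA2 dendrites by -2.61 ± 0.302 (SE, adjusted p = 3.51e-07). It was also lower in CA3 (-1.58, adjusted p = 0.000336) and DG (-1.28, adjusted p = 0.00257), and in CA1 its difference was -0.06 and did not pass (adjusted p = 0.925). Its log2 values in CA1 dendrites were 10.25 and 10.85 in mice 492 and 496, whose libraries had high medians, and 8.97 in mouse 502, against 10.04 to 10.13 in CA1 cell bodies.

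Genes called within subregions were 6166 in CA1, 6979 in CA2, 5493 in CA3 and 5545 in DG. The median difference of all genes was -0.11, -0.17, -0.18 and -0.14 (-0.17, -0.11, -0.14 and -0.22 under quantile normalization). In CA1, 3784 were higher and 2382 lower, against 3257 and 3951 under quantile normalization. In DG, 3227 were higher and 2318 lower, against 3477 and 3718, and in CA3 2644 were higher and 2849 lower. In CA2, 2682 were higher and 4297 lower. Scaling to totals gave more lower than higher genes in each subregion (2135 higher and 7624 lower in CA1, 2554 and 5088 in CA2, 2317 and 4579 in CA3, 2281 and 6178 in DG). Totals outside the mitochondrial genome gave the opposite in CA2 (4008 higher and 2496 lower) and CA3 (3217 and 2473). Without mouse 502 the counts in CA2, CA3 and DG fell to 4592, 3569 and 3424, and without the 4 dendritic libraries that have a repeat, CA2 and DG gave 3980 and 3242.

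CA1 dendrites were compared with the mean of the other dendrites. Mpped1 (chromosome 15, 83779467 to 83858494), a CA1 marker that encodes a metallophosphoesterase domain protein, was higher by 3.78 ± 0.214 (SE, adjusted p = 3.23e-11), with mean log2 values of 14.32 ± 0.281 (SD) in CA1 and 10.97 ± 0.158, 10.53 ± 0.159 and 10.1 ± 0.637 in CA2, CA3 and DG dendrites. Wfs1 (chromosome 5, 36966104 to 36989205), an endoplasmic reticulum gene used as a CA1 marker, was higher by 2.95 ± 0.297 (SE, adjusted p = 2.77e-07). Itpka, a dendritic inositol phosphate kinase, was higher by 2.71 ± 0.222 (SE). Cyp26b1 (chromosome 6, 84571414 to 84593908), which encodes an enzyme that degrades retinoic acid, was lower by -7.10 ± 0.776 (SE, adjusted p = 9.54e-07). Spef2 was lower by -6.45 ± 0.577 (SE).

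Of 10 CA1 markers, 9 were higher in CA1 dendrites (9 adjusted over the list alone), with a median log2 difference of 2.73, or 2.58 relative to all genes (adjusted p = 0.00142 with an estimated correlation). Of 26 postsynaptic scaffold genes, 22 were higher (25 adjusted over the list alone), with a median of 1.12, or 0.96 relative to all genes, led by Homer2 (2.08), Psd (1.41) and Shank1 (1.35). The scaffold list had a camera adjusted p = 8.2e-21, and adjusted p = 0.0959 with an estimated correlation, and under quantile normalization its median was 0.41 with 16 higher. Of 81 ribosomal protein genes, 62 were higher (73 adjusted over the list alone; median 0.86, Rps16 1.55), and 11 under quantile normalization with a median of 0.33 (camera adjusted p = 1.1e-20, and adjusted p = 0.27 with an estimated correlation). Of 16 textbook dendritic mRNAs, 13 were higher (16 adjusted over the list alone; median 1.11, Ddn 1.44), with a median of 0.42 under quantile normalization (camera adjusted p = 7.72e-14, and adjusted p = 0.0676 with an estimated correlation). Of 13 immediate early genes, 7 were higher (10 adjusted over the list alone; median 1.45, Arc 2.08, Nr4a1 1.59), and 3 under quantile normalization with a median of 1.09 (camera adjusted p = 2.14e-05, and adjusted p = 0.247 with an estimated correlation). Of 13 oligodendrocyte markers, 7 were lower (8 adjusted over the list alone; median -0.77, Mbp -0.90; camera adjusted p = 4.77e-08, and adjusted p = 0.247 with an estimated correlation). Of 12 microglia markers, 8 were higher (10 adjusted over the list alone; median 0.85, or 0.69 relative to all genes), and 0 in limma under quantile normalization with a median of 0.33 (camera adjusted p = 2.14e-05, and adjusted p = 0.0959 with an estimated correlation).

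In CA1 dendrites 3297 genes differed, 2685 higher and 612 lower, which quantile normalization changed to 705 higher and 853 lower and scaling to totals to 441 and 1601. The median of all genes was 0.16 (-0.02 under quantile normalization and -0.36 under scaling to totals). Without the CA1 dendritic libraries of mice 492 and 496, only that of mouse 502 was left, and the median of all genes was 0.04. Without all libraries of mouse 496 or of mouse 492, 1485 and 1435 genes were called.

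CA2 dendrites were compared with the mean of the other dendrites. Necab2 (chromosome 8, 119446719 to 119472640), which encodes a neuronal calcium-binding protein, was higher by 1.83 ± 0.233 (SE, adjusted p = 3.3e-05). Rgs14 (chromosome 13, 55369732 to 55384687), a regulator of G-protein signalling and a CA2 marker, was higher by 1.54 ± 0.206 (SE, adjusted p = 6.02e-05), with a mean log2 value of 11.41 ± 0.086 (SD) in CA2 dendrites and 10.95 ± 0.435 in CA1 dendrites. Ptpn5 was higher by 1.12 and Sostdc1 by 4.49. Iqsec2 (X chromosome, 152144268 to 152225236), which encodes an exchange factor of excitatory synapses, was lower by -1.27 ± 0.134 (SE, adjusted p = 2.62e-06). Htr4, a serotonin receptor gene, was lower by -4.04 ± 0.737 (SE). Amigo2 (chromosome 15, 97244125 to 97247287), the gene of the reporter line, differed by 0.76 ± 0.27 (SE, adjusted p = 0.162), Pcp4 (chromosome 16, 96467606 to 96525793) by 0.89 ± 0.466 (SE, adjusted p = 0.401) and Mcu by -0.17 ± 0.247 (SE, adjusted p = 0.83), and none passed.

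Of 15 CA2 markers, 4 were higher in CA2 dendrites (5 adjusted over the list alone), with a median of 0.91, or 0.98 relative to all genes (adjusted p = 0.0204 with an estimated correlation). Of 26 postsynaptic scaffold genes, 13 were lower and 1 higher (17 and 1 adjusted over the list alone), with a median of -0.61, or -0.54 relative to all genes, and with Cnksr2 at -1.01 and Agap2 at -0.83. The scaffold list had a camera adjusted p = 7.84e-12, and adjusted p = 0.341 with an estimated correlation, and under quantile normalization its median was -0.25 with 9 lower and 2 higher. Of 16 textbook dendritic mRNAs, 10 were lower (12 adjusted over the list alone; median -0.64, Psd -1.10, Itpka -1.54), and 5 under quantile normalization with a median of -0.30 (camera adjusted p = 2.87e-12, and adjusted p = 0.0603 with an estimated correlation). Of 14 interneuron markers, 1 was higher, Gad2 at 0.54 (3 adjusted over the list alone), with a list median of 0.55 (camera adjusted p = 5.03e-06, and adjusted p = 0.192 with an estimated correlation), a call lost without the 4 libraries that have a repeat. The interneuron list mean was 11.64 in CA2 dendrites, below 11.81 in CA3 dendrites, with 11.24 in CA1 and 10.31 in DG dendrites. Of 8 choroid and ependymal markers, 3 were higher (3 adjusted over the list alone), Ttr by 5.56 ± 0.946 (SE, adjusted p = 0.000998), Clic6 by 5.07 and Tmem212 by 4.37, with a list median of 1.76 (adjusted p = 0.0204 with an estimated correlation).

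Mitochondrial groups were examined in CA2 dendrites because the series title names them. Of 37 nuclear genes of respiratory complex I, limma called 0 (0 adjusted over the list alone, 1 at an unadjusted p below 0.05), with a median of 0.14 (camera adjusted p = 0.0542). Under quantile normalization 1 was higher, the median was 0.38 and the list passed camera at the preset correlation (adjusted p = 8.88e-06). An estimated correlation was not tried under that normalization. Of 25 genes of complexes II to IV, limma called 0 (0 adjusted over the list alone, 3 unadjusted), with a median of 0.16 (camera adjusted p = 0.0396, and adjusted p = 0.884 with an estimated correlation), and 4 were higher under quantile normalization. Of the 13 mitochondrial genome mRNAs, limma called 0 (0 adjusted over the list alone, 0 unadjusted), with a median of 0.21 (camera adjusted p = 0.0357, and adjusted p = 0.884 with an estimated correlation). Of 12 genes of mitochondrial calcium handling, limma called 0 (0 adjusted over the list alone, 1 unadjusted), with a median of 0.01 (camera adjusted p = 0.863).

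In CA2 dendrites 640 genes differed, 111 higher and 529 lower, against 262 higher and 399 lower under quantile normalization, and 339 higher and 273 lower under scaling to totals outside the mitochondrial genome. The median of all genes was -0.07 (0.00 under quantile normalization, 0.02 under scaling to totals). Without mouse 492 the count was 130 and without mouse 496 it was 172, and without the 4 libraries that have a repeat it was 57, of which 49 were among the 640.

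**Figure D3:**
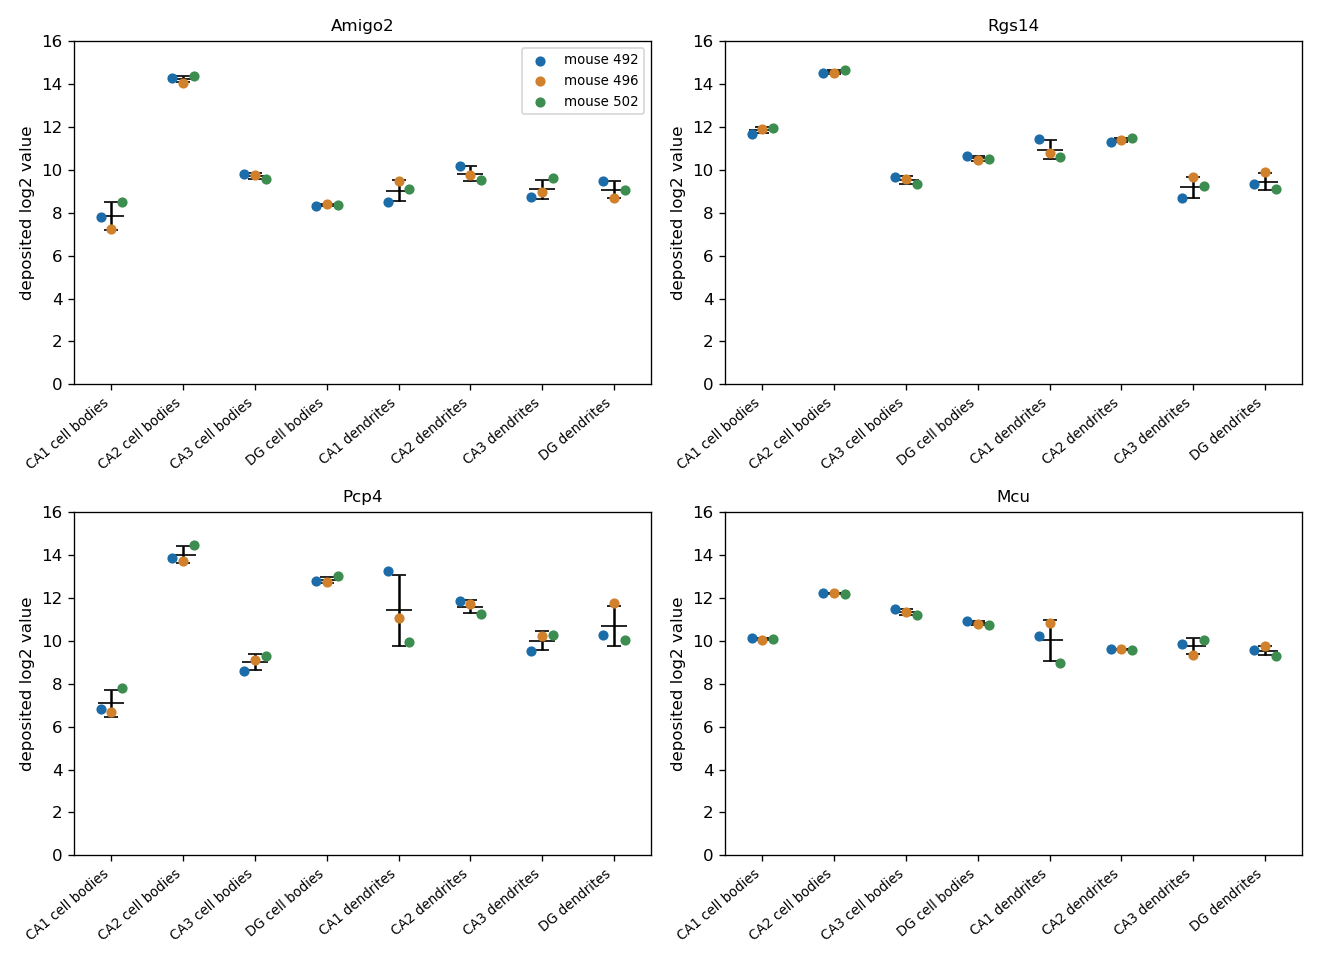
Deposited log2 values (vertical axis) of Amigo2, Rgs14, Pcp4 and Mcu in 8 groups; points are libraries coloured by mouse, and bars are mean ± SD of 3 mice. In CA2 the mean of Amigo2 is 14.23 in cell bodies and 9.83 in dendrites, that of Rgs14 14.56 and 11.41, that of Pcp4 14.02 and 11.60, and that of Mcu 12.22 and 9.61.

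**Figure D4:**
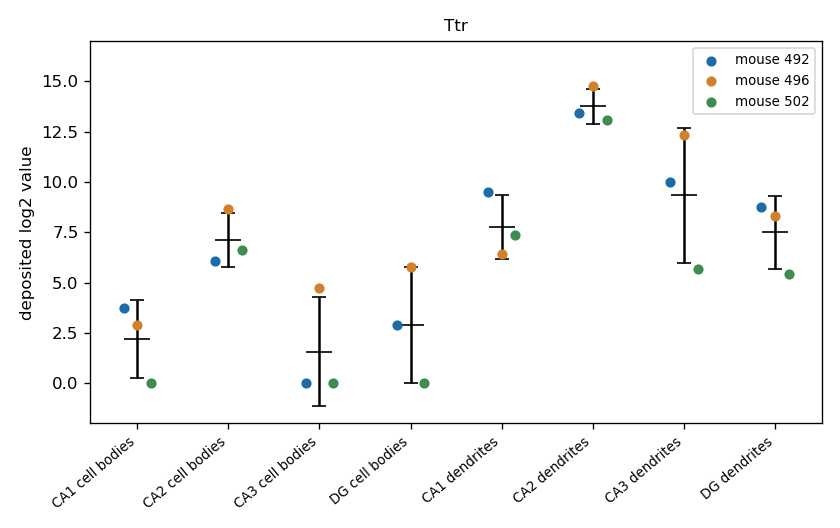
Deposited log2 values (vertical axis) of Ttr in 8 groups; points are libraries coloured by mouse, and bars are mean ± SD of 3 mice. The mean in CA2 dendrites is 13.76 ± 0.892, and in the other dendrites it is 7.50 to 9.34, with the CA3 dendritic library of mouse 496 at 12.3.

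CA3 dendrites were compared with the mean of the other dendrites. Bok (chromosome 1, 93685660 to 93695764), a Bcl-2 family gene and CA3 marker, was higher by 3.13 ± 0.293 (SE, adjusted p = 4.4e-07), with mean log2 values of 11.74 ± 0.332 (SD) in CA3 dendrites and 11.82 ± 0.078 in CA3 cell bodies. Cyp26b1 was higher by 5.04 ± 0.776 (SE, adjusted p = 0.000406), and it was lower in CA1 dendrites, which are part of the mean compared. Syn2 (chromosome 6, 115134902 to 115282006), a synaptic vesicle protein gene, was higher by 1.41 ± 0.143 (SE, adjusted p = 1.12e-06). Slc17a8 (chromosome 10, 89574020 to 89621253), a vesicular glutamate transporter gene of a subset of interneurons, was higher by 3.04 ± 0.606 (SE). Slc17a8 was lower in DG dendrites, which are part of the mean compared here. Lum, a proteoglycan gene, was lower by -5.15 ± 1.17 (SE).

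Of 8 CA3 markers, 3 were higher in CA3 dendrites (6 adjusted over the list alone), with a median of 1.65 (adjusted p = 0.000663 with an estimated correlation), among them Homer3 (1.63) and Grik4 (1.67). Of 29 presynaptic vesicle genes, 13 were higher (21 adjusted over the list alone), with a median of 0.75, or 0.77 relative to all genes, including Bsn (0.99), Slc17a7 (0.88) and Cplx1 (0.79) (camera adjusted p = 9.46e-12, and adjusted p = 0.244 with an estimated correlation). This list was lower in DG dendrites, which are part of the mean compared, and how much of the CA3 difference comes from them was not tested. Of 14 interneuron markers, 6 were higher (11 higher and 1 lower adjusted over the list alone), with a median of 0.88, Gad1 at 0.98 and Slc32a1 at 1.37 (adjusted p = 0.0274 with an estimated correlation). The list mean was 11.81 ± 0.244 (SD) in CA3 dendrites, and 11.24, 11.64 and 10.31 in those of CA1, CA2 and DG. CA3 thus lay close to CA2, and the low DG values enter this difference. Of 11 endothelial markers, 2 were lower (4 adjusted over the list alone), Itm2a by -1.08 and Slc2a1 by -0.69, with a median of -0.67 (adjusted p = 0.00587 with an estimated correlation). Of 81 ribosomal protein genes, 2 were lower, Rplp2 by -1.12 and Rps16 by -0.89 (14 adjusted over the list alone), with a median of -0.41 (camera adjusted p = 6.11e-14, and adjusted p = 0.41 with an estimated correlation), a call that fry did not make.

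In CA3 dendrites 537 genes differed, 320 higher and 217 lower, with a median of all genes of -0.01 (0.00 under quantile normalization). Quantile normalization gave 1020 calls, and leaving out mouse 502, 496 or 492 gave 320, 193 and 140.

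DG dendrites were compared with the mean of the other dendrites. Prox1 (chromosome 1, 190118035 to 190170714), a transcription factor gene of granule cells, was higher by 2.06 ± 0.29 (SE, adjusted p = 3.71e-05), with mean log2 values of 13.64 ± 0.317 (SD) in DG dendrites and 15.01 ± 0.116 in DG cell bodies. C1ql2 (chromosome 1, 120340582 to 120343174), a synaptic organizer gene of granule cells, was higher by 3.22 ± 0.758 (SE, adjusted p = 0.00812). Slc17a8 was lower by -6.74 ± 0.606 (SE, adjusted p = 5.89e-08). Rab3c, a synaptic vesicle gene, was lower by -1.63 ± 0.16 (SE).

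Of 12 granule cell markers, 6 were higher in DG dendrites (8 adjusted over the list alone), with a median of 1.75, or 1.80 relative to all genes, including Trpc6 (2.36) and Pdzd2 (1.44) (adjusted p = 0.0355 with an estimated correlation). Of 29 presynaptic vesicle genes, 21 were lower and 1 higher (22 and 2 adjusted over the list alone), with a median of -1.09, Cplx1 at -1.33 and Syt1 at -1.37 (camera adjusted p = 1.02e-13, and adjusted p = 0.164 with an estimated correlation). Of 14 interneuron markers, 9 were lower (9 adjusted over the list alone), with a median of -1.30, Gad2 at -1.52 and Sst at -2.23 (adjusted p = 0.0297 with an estimated correlation). Of 26 postsynaptic scaffold genes, 15 were lower (19 adjusted over the list alone), with a median of -0.58, Shank1 at -1.25 and Homer2 at -1.46 (camera adjusted p = 5.52e-13, and adjusted p = 0.173 with an estimated correlation). Under quantile normalization the scaffold median was -0.17, with 10 lower and 2 higher. CA1 dendrites, where this list was higher, are part of the mean compared, and how much of the DG difference comes from them was not tested. Of 37 nuclear genes of complex I, 7 were lower (13 adjusted over the list alone), with a median of -0.56 and Ndufa5 at -1.12 (camera adjusted p = 8.76e-08, and adjusted p = 0.3 with an estimated correlation), and 2 under quantile normalization. The complex I call was lost without the 4 libraries that have a repeat.

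In DG dendrites 1733 genes differed, 338 higher and 1395 lower, against 717 higher and 964 lower under quantile normalization, and 947 higher and 579 lower under scaling to totals. The median of all genes was -0.05 (0.03 under quantile normalization, 0.32 under scaling to totals). Leaving out mouse 492 or 502 gave 670 and 1009 genes, and leaving out the 4 libraries that have a repeat gave 241.

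**Figure D5:**
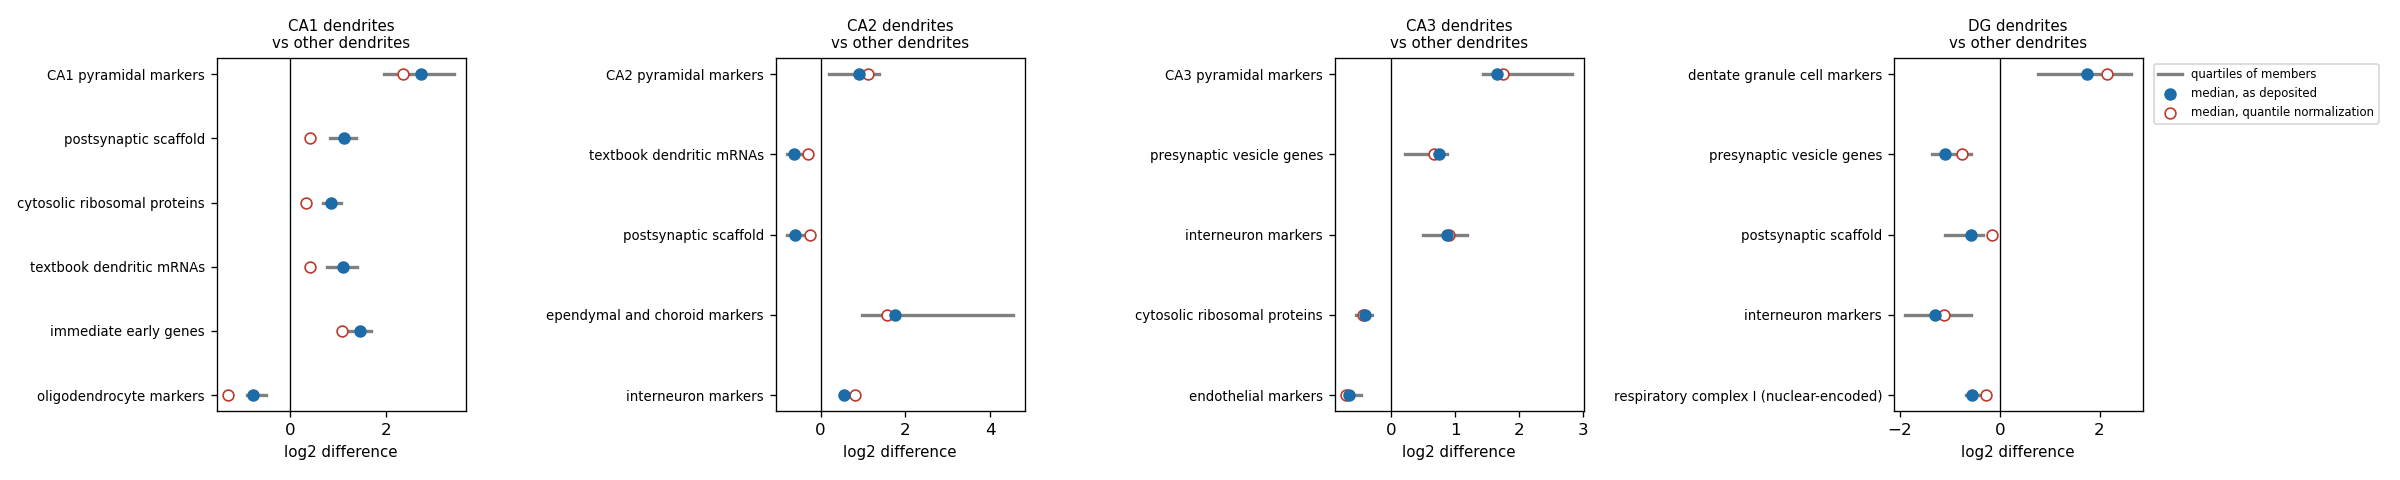
Log2 difference (horizontal axes) between the dendrites of each subregion and the mean of the other dendrites for the gene lists of each comparison, 3 mice per group; filled points are list medians of the deposited values, open points are medians under quantile normalization, and grey bars span the quartiles of the members. The own markers of CA1, CA2, CA3 and DG have medians of 2.73, 0.91, 1.65 and 1.75, and no list median shown changes sign under quantile normalization.

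Cell bodies of each subregion were compared with the mean of the other cell bodies, as a reference for the dendritic differences. In CA1, Wfs1 was higher by 5.32 ± 0.297 (SE) and Mpped1 by 5.05 ± 0.214. All 10 CA1 markers were higher (10 adjusted over the list alone; median 5.19, adjusted p = 5.43e-07 with an estimated correlation). Of 13 immediate early genes, 9 were higher in CA1 (9 adjusted over the list alone; median 1.58, Nr4a1 2.75, Arc 2.32, adjusted p = 0.0175 with an estimated correlation). Of 13 oligodendrocyte markers, 11 were lower (12 adjusted over the list alone; median -1.24, Mbp -1.46, adjusted p = 0.0223 with an estimated correlation).

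In CA2 cell bodies, Avpr1b (chromosome 1, 131599239 to 131612000), a vasopressin receptor gene, was higher by 8.01 ± 1.07 (SE, adjusted p = 1.02e-05). Amigo2, the gene of the reporter line, was higher by 5.59 ± 0.27 (SE, adjusted p = 1.05e-12), which checks the capture of CA2 cell bodies. Of 15 CA2 markers, 13 were higher (14 adjusted over the list alone; median 4.37, or 4.27 relative to all genes, adjusted p = 4.06e-05 with an estimated correlation). Mcu was higher by 1.47 ± 0.247 (SE, adjusted p = 0.000195). Means of several cell type marker lists were also highest in CA2 cell bodies. They were 8.63 for endothelial markers (7.97, 8.41 and 7.32 in CA1, CA3 and DG) and 10.01 for interneuron markers (9.71, 9.44 and 8.57). For astrocyte markers the mean was 10.99 (10.42, 10.83 and 10.28). The lists below were not separated from them. Of 16 glycolysis genes, 12 were higher (15 adjusted over the list alone; median 0.68, or 0.58 relative to all genes, Pgam1 0.98, Gpi1 1.21), and 8 under quantile normalization. Of 17 citric acid cycle genes, 10 were higher (12 adjusted over the list alone; median 0.70, or 0.60 relative to all genes, Pdha1 1.17), and 5 under quantile normalization. Of 37 complex I genes, 6 were higher (9 adjusted over the list alone; median 0.56, or 0.46 relative to all genes, Ndufa4 1.13), and 1 under quantile normalization. Of 13 mitochondrial genome mRNAs, 11 were higher (13 adjusted over the list alone; median 0.93, or 0.83 relative to all genes, mt-Co3 0.89), and 6 under quantile normalization. These 4 lists passed camera (adjusted p = 6.83e-09, 3.24e-07, 6.79e-07 and 4.31e-08), with quantile medians of 0.31, 0.31, 0.25 and 0.39, and none passed with an estimated correlation (adjusted p = 0.223, 0.224, 0.383 and 0.271 with an estimated correlation). Of 13 oligodendrocyte markers, 10 were higher in CA2 cell bodies (12 adjusted over the list alone; median 1.06, Mbp 0.94, Mobp 1.19; camera adjusted p = 6.83e-09, and adjusted p = 0.151 with an estimated correlation), and 5 under quantile normalization.

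In CA3 cell bodies, Bok was higher by 4.12 ± 0.293 (SE), and 7 of 8 CA3 markers were higher (8 adjusted over the list alone; median 3.76, adjusted p = 1.41e-05 with an estimated correlation). Of 29 presynaptic vesicle genes, 14 were higher and 1, Sv2c, was lower (20 and 1 adjusted over the list alone; median 0.74, Bsn 1.69, Syn2 1.80; camera adjusted p = 7.42e-10, and adjusted p = 0.293 with an estimated correlation). Of 13 oligodendrocyte markers, 11 were higher in CA3 cell bodies as well (12 adjusted over the list alone; median 1.19, camera adjusted p = 8.93e-15, and adjusted p = 0.0541 with an estimated correlation). In DG cell bodies, Prox1 was higher by 6.44 ± 0.29 (SE) and C1ql2 by 10.10 ± 0.758 (SE). Of 12 granule cell markers, 11 were higher (11 adjusted over the list alone; median 5.16, adjusted p = 0.000946 with an estimated correlation). All 16 glycolysis genes were lower in DG (16 adjusted over the list alone; median -1.22, or -1.14 relative to all genes, Ldha -1.82, Pfkp -1.74), and 13 under quantile normalization with a median of -0.60 (camera adjusted p = 3.64e-13, and adjusted p = 0.147 with an estimated correlation). Of 37 complex I genes, 17 were lower in DG (32 adjusted over the list alone; median -0.68, Ndufs8 -0.91), and 3 under quantile normalization with a median of -0.25 (camera adjusted p = 2.63e-07, and adjusted p = 0.348 with an estimated correlation). In the same DG cell bodies, of 11 endothelial markers, 7 were lower (11 adjusted over the list alone; median -1.01, adjusted p = 0.00536 with an estimated correlation), and of 14 interneuron markers 11 were lower and 1 higher (11 and 1 adjusted over the list alone; median -1.31, camera adjusted p = 4.59e-06, and adjusted p = 0.147 with an estimated correlation).

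Genes called in cell bodies were 1490 in CA1 (698 higher), 2235 in CA2 (1828 higher), 1753 in CA3 (1224 higher) and 4291 in DG (870 higher). Under quantile normalization 1024 were higher and 845 lower in CA2, 1033 and 824 in CA3, and 1710 and 1964 in DG. Scaling to totals turned the balance, with 822 higher and 1235 lower in CA2, 786 and 1048 in CA3, and 2637 and 1289 in DG, and in CA1 it gave 953 and 857. The median of all genes was 0.01, 0.10, 0.04 and -0.08 (0.00, -0.02, 0.00 and 0.00 under quantile normalization). Leaving out mouse 502, 496 or 492 gave 838, 935 and 921 genes in CA1, 1015, 1372 and 1316 in CA2, and 996, 1062 and 907 in CA3, and leaving out mouse 502 gave 2685 in DG.

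The difference of CA2 from the other subregions was then compared between dendrites and cell bodies, to test directly whether CA2 stands apart to the same extent in both. Necab2 had a difference in dendrites that was smaller than in cell bodies by a log2 value of -2.84 ± 0.33 (SE, adjusted p = 5.53e-06). Rgs14 gave -2.37 ± 0.291 (SE, adjusted p = 1.25e-05) and Amigo2 -4.83 ± 0.382 (SE, adjusted p = 6.35e-08). Mcu gave -1.63 ± 0.349 (SE, adjusted p = 0.00412), and under quantile normalization -1.15 without passing (adjusted p = 0.0667). Of 15 CA2 markers, 10 gave negative differences that passed (12 adjusted over the list alone; median -2.84, or -2.63 relative to all genes, adjusted p = 0.00163 with an estimated correlation). The own marker lists of CA1, CA3 and DG also had smaller medians in dendrites than in cell bodies, without a test of this kind. Of 26 postsynaptic scaffold genes, 22 gave negative differences that passed (23 adjusted over the list alone; median -1.02, or -0.81 relative to all genes, Agap2 -1.52, Iqsec2 -1.27). For the scaffold list, quantile normalization left a median of -0.26 with 2 negative and 1 positive (camera adjusted p = 1.15e-13, and adjusted p = 0.2 with an estimated correlation). The test called 1786 genes, 183 positive and 1603 negative, against 303 positive and 366 negative under quantile normalization, 348 and 359 under scaling to totals, and 585 and 327 under totals outside the mitochondrial genome, with a median of all genes of -0.21 (0.01 under quantile normalization, 0.27 under scaling to totals). Leaving out mouse 502, 496 or 492 gave 986, 502 and 546 genes.

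Transcripts of the same gene were compared to ask whether compartments hold different isoforms. Gpm6b, a myelin and neuronal membrane glycoprotein gene with 7 transcripts tested, had 1 transcript higher in dendrites by 7.07 (mean log2 values 13.9 and 6.8) and 1 lower by -5.27 (7.34 and 12.6), with diffSplice adjusted p = 6.94e-62. Macf1, a cytoskeletal crosslinker gene, had transcripts at 3.19 and -3.09, and Kalrn, an exchange factor gene of spines, at 2.76 and -4.14. In all, 1978 of 10025 genes changed unequally between compartments (3271 at an unadjusted p below 0.05). Markers of glia, vessels and interneurons were higher in the dendritic layers, so an unequal change can also come from a different mix of cells. Which cells the transcripts come from was not tested. In CA2 dendrites 153 genes did so (1534 unadjusted), among them Mbp (2.25 and -4.31, adjusted p = 3.09e-05), Iqsec2 (2.30 and -1.60, adjusted p = 5.37e-05) and Shank2 (1.72 and -1.97, adjusted p = 0.000329). Leaving out mouse 502, 496 or 492 gave 1020, 1011 and 1261 genes between compartments, and 120, 160 and 92 in CA2 dendrites, of which 59, 47 and 31 were among the 153. Without the 4 libraries that have a repeat, 38 were called in CA2 dendrites, 10 of them among the 153.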

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

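Of the tests of explanations in this part, that on a second set of choroid genes was planned before its result was seen, quantile normalization was a planned setting whose use as a test of an explanation was chosen after its results were seen, and the other tests were chosen only after their results were seen.

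The difference between CA2 and the other subregions was not the same in dendrites as in cell bodies, by limma's test of that difference itself, for 1786 genes. It was more positive in dendrites for C1qtnf6 (4.66 ± 1.27, SE, adjusted p = 0.025), Lbp (4.54 ± 1.29, adjusted p = 0.032), Spef2 (3.54 ± 0.816, adjusted p = 0.00748) and Sema5b (3.27 ± 0.77, adjusted p = 0.00879). CA2 was set against the mean of the other subregions, so 1 of those can also produce such a difference. Spef2 was lower in CA1 dendrites, and Sema5b is on the granule cell marker list. The difference was more negative for Tmem215 (-6.41 ± 1.31, adjusted p = 0.00284), Scube2 (-5.93 ± 1.48, adjusted p = 0.0137), Cacng5 (-5.72 ± 0.574, adjusted p = 9.99e-07) and St8sia6 (-5.36 ± 0.687, adjusted p = 2.11e-05). Of the CA2 genes followed throughout, it was more negative for Amigo2 (-4.83), Rgs14 (-2.37), Pcp4 (-3.48) and Mcu (-1.63), of which Mcu did not pass under quantile normalization (-1.15, adjusted p = 0.0667). Among lists, CA2 markers gave a median of -2.84 and postsynaptic scaffold genes a median of -1.02. The own markers of CA1, CA3 and DG also had smaller list medians in dendrites than in cell bodies. A smaller marker difference in dendrites was thus not particular to CA2, and the difference between compartments was tested for CA2 only. The scaffold call did not hold with an estimated correlation (adjusted p = 0.2), and under quantile normalization its median was -0.26, with 2 genes negative and 1 positive against 22 negative on the deposited values. The count was 1786 genes, against at most 1586 in any other of 64 splits. That other split calls nearly as many, and splits that mix subregions gave at most 155, so the high counts follow the subregions themselves. The splits thus rank CA2 just ahead of another subregion and cannot decide on chance. The count also depends on scaling, with 669 genes under quantile normalization, 303 positive and 366 negative.

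More genes were higher (2685) than lower (612) in CA1 dendrites. The share of higher calls came to 45.3% under quantile normalization, but that method gives all libraries the same distribution and so sets this balance whatever the cause. Whether the deposited normalization left the CA1 dendritic libraries high, or these libraries differ in RNA content, cannot be told apart from this share. The tables argue against the deposited normalization as the whole cause for postsynaptic scaffold genes, whose list median stayed at 0.41 under quantile normalization (adjusted p = 1.59e-11). The scaffold call itself did not hold with an estimated correlation (adjusted p = 0.0959).

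The postsynaptic scaffold list was called lower in CA2 dendrites, with 13 of 26 genes lower and 1 higher. Under quantile normalization the list median was -0.25 (adjusted p = 0.000208), which argues against the deposited normalization as the whole cause, although with an estimated correlation the call did not hold (adjusted p = 0.341). The estimated correlation was tried on the deposited values only. Interneuron markers exceeded microglia markers, relative to the other dendrites, by 0.825 ± 0.046 (SD, n = 3), whereas a general loss of pyramidal cell RNA would by itself raise both alike. The gap was 1.22 ± 0.274 against CA1 and 1.52 ± 0.218 against DG but -0.262 ± 0.123 against CA3 dendrites, each over 2 SD. The bound for each subregion was set, and once changed, with the values seen. The compared layers themselves differed in these markers. The interneuron list mean was 10.31 in DG dendrites and 11.24 to 11.81 in the others. The microglia list mean was 11.6 in CA1 dendrites and 10.69 to 10.97 in the others. The gap therefore cannot decide on a loss of pyramidal cell RNA. How the make-up of the compared layers, or an untested difference of CA2 itself, enters is left open. Whether the high CA1 libraries produce the difference cannot be told apart: against CA3 and DG dendrites the median was -0.29, with 4 genes lower and 1 higher (adjusted p = 0.00485, with an estimated correlation 0.968), but under quantile normalization it was -0.12 (adjusted p = 0.184), and the requirement that both scalings pass was added after these values were seen.

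Choroid and ependymal markers, led by Ttr, were higher in CA2 dendrites. A second set of such genes, written down before it was looked at, had a median of 1.45, with 17 of 17 tested genes above 0 and 2 past the threshold, Enpp2 (0.90) and Slc4a5 (5.06) (camera p = 2.07e-09, and 0.00231 with an estimated correlation). RNA of choroid plexus or ependyma in these captures is a candidate explanation that this test bears out. A stray library alone is argued against, since the list mean was above the other dendrites of the same mouse in 3 of 3 mice, by 1.40, 3.10 and 3.10 in mice 492, 496 and 502. Ttr had log2 values of 13.4, 14.8 and 13.1 in those CA2 dendritic libraries, and 12.3 in the CA3 dendritic library of mouse 496.

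The count of genes was compared with counts from other splits of the libraries. A first version of these splits fitted 2 groups at a time, and a second, in which the subregion labels were exchanged within each mouse in the full fit, was added after the first had been seen. For the mean of compartments chance can be excluded in the second version (11269, and at most 8293 in the other of 100 splits). For each subregion alone the 10 splits are too few, with 6166, 6979, 5493 and 5545 genes and at most 0, 2, 0 and 0 in other splits. Of 64 splits, 1 gave as many genes as CA1 dendrites (3297, highest other 1733) and 2 as many as DG dendrites (1733, highest other 3297). The highest other splits are those of DG and of CA1 dendrites, so these numbers rank whole subregions and cannot decide on chance. Both counts were above all splits that mixed subregions (at most 1028 and 1536). Chance cannot be excluded for CA2 dendrites (640, with 4 splits as large, highest other 3297) or CA3 dendrites (537, with 9 as large, highest other 3297), where the splits with more calls include those that follow CA1 or DG. In cell bodies 4 splits were as large for CA1 (1490) and 2 for CA2 (2235). For CA3 (1753) there were 3, and for DG (4291, highest other 2235) 1. Splits that mix subregions gave at most 797, 1195, 1195 and 797, so the splits as large were those that follow whole subregions. These numbers rank the subregions by their count and so cannot decide on chance for any of them. The count of each subregion was above all splits that mix subregions. The highest other split for CA1, CA2 and CA3, with 4291, was that of DG. For transcripts chance can be excluded between compartments (1978, highest other 841) but not in CA2 dendrites (153, with 23 splits as large and 843 the highest other). Splits that mixed subregions gave at most 1028, 1536, 1230 and 1536 genes in the 4 dendritic comparisons and 797, 1195, 1195 and 797 in cell bodies. The first version gave 9368 between compartments (highest other 6376), 666, 1, 2 and 277 in the dendrites of CA1, CA2, CA3 and DG, 452, 462, 239 and 4532 in cell bodies, and 62 for the difference between compartments (highest other 359). There 6 splits were as large as CA2 dendrites, 3 as CA3 dendrites, 3 as CA1 cell bodies and 4 as CA3 cell bodies. That version put the other subregions into 1 group, so their differences counted as spread, and it called only 1 and 2 genes in CA2 and CA3 dendrites. No verdict on chance for a subregion is drawn from it. Transcripts in that version gave 1555 genes between compartments (highest other 648) and 2 in CA2 dendrites (highest other 41).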

How the results depend on the processing

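Median scaling, totals outside the mitochondrial genome, and leaving out the CA1 dendritic libraries of mice 492 and 496 were tried only after the data were seen, and the other settings were planned. Of list results under all settings, 854 kept direction and side of the threshold, 42 lost the threshold and 3 reversed. Of named gene results 4422 kept both, 663 lost the threshold, 12 gained it and 21 reversed. Of the 48 list calls followed through the settings that apply to them, 20 held with an estimated correlation and 28 did not. Those that held were the astrocyte, microglia, oligodendrocyte, endothelial and interneuron lists in the mean of compartments, the own markers of each subregion in its dendrites and cell bodies, choroid markers in CA2 dendrites, interneuron and endothelial markers in CA3 dendrites, interneuron markers in DG dendrites, immediate early genes and oligodendrocyte markers in CA1 cell bodies, and CA2 markers in the difference between compartments. Outside these 48 other lists held too, among them the own markers of CA1, CA2 and CA3 between their compartments, perineuronal net genes in the mean of compartments and endothelial markers in DG cell bodies. Beyond the estimated correlation, interneuron markers in CA2 dendrites (adjusted p = 0.0858) and complex I in DG dendrites (adjusted p = 0.76) lost their calls without the 4 libraries that have a repeat, ribosomal proteins in CA3 dendrites under fry (adjusted p = 0.068), and textbook mRNAs in the mean of compartments without shared members (adjusted p = 0.967). The covariates ended the calls of astrocyte, microglia, oligodendrocyte, interneuron and mitochondrial genome lists in the mean of compartments, oligodendrocyte markers in CA1 dendrites and in CA1 and CA2 cell bodies, ribosomal proteins in CA3 dendrites and the citric acid cycle in CA2 cell bodies. Quantile normalization kept all 48 lists and 300 named genes, while 25 named genes lost the threshold. Without the replicate block the counts were 11120, 6015, 6778, 5365 and 5367 between compartments, 3043, 558, 489 and 1568 in dendrites, and 1586 for the difference between compartments. Except where fewer libraries explain a lower count, the cause was not tested.

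With the astrocyte and oligodendrocyte means as covariates limma called 0 genes in all 5 comparisons between compartments, 425 in CA1 dendrites, 269, 113, 212 and 477 in the cell bodies of CA1, CA2, CA3 and DG, and 14 for the difference between compartments. The reversed results all arose there. In the mean of compartments the list medians became -1.72 (cytosolic ribosomal proteins, dendrites vs cell bodies, mean of 4 subregions), -1.86 (scaffold) and -0.39 (textbook dendritic), while the median of all genes became -1.71, so the textbook list stayed above it. Among genes, Acot3 became 11.70, Thpo 14.70, C2cd4a 4.38, Gemin6 30.80, Fgf5 3.03, Lrrc26 6.00 and Psmb5 0.17. Gad1 became -0.36, Erbb4 -1.44, Mbp -0.62, P2ry12 -1.54, Cx3cr1 -0.81, Flt1 -0.14, Camk2a -0.28, Shank1 -0.46, Map2 -0.33, mt-Co1 -0.56, mt-Atp6 -0.36, Rps29 -1.66 and Rplp0 -0.66. Pcp4 in CA1 dendrites against CA1 cell bodies became -0.19. The means had r = 0.988 and 0.912 with compartment, so these values extrapolate.

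Library weights gave 4146, 5028, 4908 and 10053 genes in cell bodies, 673, 355 and 256 in CA1, CA2 and CA3 dendrites, and 8589 between DG compartments. Only the libraries of the compartment or subregion gave 3737, 6285, 4537 and 7865 in cell bodies, 1396, 287, 220 and 918 in dendrites, and 2561 between CA1 compartments. Quantile normalization gave 1558 in CA1 dendrites, 1020 in CA3 dendrites and 669 for the difference between compartments. Scaling to totals gave 9759 and 8459 between CA1 and DG compartments, 2042 and 895 in CA1 and CA3 dendrites, and 707 for the difference. Median scaling gave 1910, 1021 and 1086 for CA1 dendrites, CA3 dendrites and the difference, and totals outside the mitochondrial genome 949 and 912 for the latter pair. Genes detected at 100 counts in DG cell bodies were 11511.

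Leaving out the 4 dendritic libraries with a repeat left 1 mouse in those groups, assumed to vary like the other groups. It gave 3980 and 3242 genes between CA2 and DG compartments, 1719, 57, 227 and 241 in the 4 dendrites, 848 for the difference, and 1167 and 38 for transcripts. Leaving out the CA1 dendritic libraries of mice 492 and 496 gave 424 in CA1 and 927 in CA3 dendrites. Leaving out each mouse gave 4592 to 5938, 3569 to 4294 and 3424 to 4275 genes between CA2, CA3 and DG compartments. Dendrites gave 1435 to 3083 (CA1), 130 to 623 (CA2), 140 to 320 (CA3) and 670 to 1197 (DG). Cell bodies gave 838 to 935, 1015 to 1372, 907 to 1062 and 2685 to 3053, the difference 502 to 986, and transcripts 1011 to 1261 and 92 to 160.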

Other observations

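The genes and lists below were chosen for mention only after their values were seen, and no explanation was tested for them.

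Perineuronal net and matrix genes, some of which are made by glia, differed by compartment and subregion. Between compartments 9 of 15 were higher in dendrites and 1 lower (9 and 1 adjusted over the list alone; median 2.30, adjusted p = 0.0466 with an estimated correlation), including Ptprz1 (2.93) and Hapln1 (3.09), and all 14 astrocyte markers were higher in the same comparison (median 3.34). In CA2 cell bodies, Acan was higher than in the other cell bodies by 4.49 ± 0.482 (SE) and Hapln4 by 3.46 ± 0.232 (SE), whereas Tnr was lower by -1.06. Of the 15 genes, 6 were higher and 3 lower there (8 and 3 adjusted over the list alone; median 0.54, camera adjusted p = 0.0126, and adjusted p = 0.223 with an estimated correlation). Ntsr2, a receptor gene on the astrocyte list, was 5.67 times as high in CA2 cell bodies as in the mean of the others. Sv2b, a synaptic vesicle gene, was higher in CA2 cell bodies by 2.61 and in CA3 cell bodies by 2.79, and lower in DG cell bodies by -6.51, where Sv2c was higher by 4.56. The interneuron list mean was also highest in CA2 cell bodies, at 10.01 ± 0.108 (SD), with 9.71, 9.44 and 8.57 in those of CA1, CA3 and DG. Of 29 presynaptic vesicle genes, 18 were higher and 1 lower in CA2 cell bodies (21 and 2 adjusted over the list alone; median 0.73, quantile median 0.37, camera adjusted p = 1.63e-08, and adjusted p = 0.261 with an estimated correlation).

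Some genes of receptors, channels and kinases were lower in DG dendrites than in the other dendrites. Interneuron markers were lower in DG dendrites too (9 of 14, median -1.30). Cnr1 (chromosome 4, 33924593 to 33948831), the cannabinoid receptor gene, was lower by -3.87 ± 0.139 (SE, adjusted p = 3.38e-15), with mean log2 values of 11.09 ± 0.247 (SD) in DG dendrites and 14.64, 14.85 and 15.40 in those of CA1, CA2 and CA3. The potassium channel genes Kcnc2 and Kcnq5 were lower by -2.09 and -1.99. Of 38 potassium channel genes, 13 were lower and 2 higher (19 and 3 adjusted over the list alone; median -0.59, quantile median -0.28, camera adjusted p = 8.72e-05, and adjusted p = 0.24 with an estimated correlation). Of 44 metabotropic and neuromodulator receptor genes, 6 were lower and 3 higher (6 and 3 adjusted over the list alone; median -0.40, camera adjusted p = 0.0116, and adjusted p = 0.24 with an estimated correlation). Of 23 plasticity kinase and phosphatase genes, 11 were lower, among them Prkcb by -2.04 (15 adjusted over the list alone; median -0.51, quantile median -0.18, camera adjusted p = 8.32e-10, and adjusted p = 0.227 with an estimated correlation). In DG cell bodies the immediate early genes Nr4a1 and Arc were lower by -3.17 and -2.97, while Btg2 was higher by 2.20.

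The 4 repeat libraries, by their titles from CA2 and DG dendrites of mice 502 and 492 although the animal label of some differs from the title, had no column of their own in the tables, and whether the columns of those animals hold their reads is not given in the sources used here.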
